A study of Arabidopsis thaliana with 18 samples.

How the data were processed

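Expression was measured on 18 Affymetrix ATH1 arrays hybridised with biotin-labelled cRNA from whole Arabidopsis thaliana plants aged 14 days, either the wild type Col-0 or etr1-1. The etr1-1 line carries a dominant ethylene receptor allele that makes plants insensitive to ethylene. GA4 is a bioactive gibberellin, applied here as a spray in water. Preparation of the cRNA used priming with oligo(dT), per the labels' protocols. The labels give 10 groups. The 4 groups sampled at 1 h (Col-0 and etr1-1, each after water or GA4) had 3 arrays each, and the other 6 groups (water at 0 h, GA4 at 30 min and GA4 at 3 h in each genotype) had 1 array each. The array titles also begin with DV001 or DV002, which are read here as batches, though the titles do not use that word. DV001 held 1 array of each of the 10 groups, and DV002 held replicates 1 and 2 of the 4 groups at 1 h. In DV001 the arrays at 1 h have replicate number 3 and those at other times 1. Some titles in DV001 also carry the word repeat, unevenly between the genotypes, and its effect was not tested. The labels do not say whether replicates came from separately grown plants, so p-values measure the spread between these samples, which may be partly technical.

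The deposited values are intensities on a linear scale, 1 per probe set, and the software that made them is not given in the sources used here. In the deposited intensity table the mean of each array after trimming 2% at each end lay between 100.007 and 100.008, so the arrays had already been scaled to a common level. The median intensity ran from 45.3 to 49.7 over the arrays and the highest from 3231.2 to 4644.7. The number of arrays limits the precision.

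The values were used with no further scaling as log2(value + 16), so fold changes are on that scale and understate the change of dim probe sets. Of the 22810 probe sets, 64 control probe sets were left out, and probe sets with a mean log2 value under the 30 th percentile were filtered, which left 15922 for testing. Of the other probe sets, 13513 named 1 gene, 503 named several and 8730 were unlisted in the platform table used here, which leaves them unnamed but not without a gene. Names were updated through Entrez identifiers to the RefSeq table of assembly TAIR10.1, where 13436 of the 13513 matched. No gene was named from a probe set with several genes. Coordinates are not used here, except gene order to find neighbours.

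Comparisons at 1 h were fitted in limma 3.58.1 (R 4.3.3) with lmFit and eBayes with an intensity trend over the 12 arrays sampled at 1 h, with 1 term per group. The comparison of the genotypes over all 5 spray and time conditions used the 18 arrays with the condition as a term. Adjusted p-values are Benjamini-Hochberg values and the threshold was 0.05. Groups with 1 array were compared within DV001 as log2 differences with no test, and the median of a gene list was set against 10000 random lists matched on mean expression. Gene lists were tested with camera at a correlation of 0.01, with the correlation also estimated and with fry, using 1 probe set per gene (the one with the highest mean). Ratios of 3' to 5' control probe sets were compared by two-sided exact permutation tests.

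Genes were named by a rule fixed before the data were examined. It takes up to 10 of the largest rises and 10 of the largest falls per comparison among named probe sets past the threshold whose groups did not overlap (over the 18 arrays, those with the same sign in all 5 conditions), up to 4 called members of each list, and a fixed set of ethylene and gibberellin genes. Where under 5 passed in a direction, the 5 with the smallest unadjusted p are named as not passing. Of the fixed set only GID1A, GID1B, GASA9 and EXPA8 were tested with a name. ETR1 itself is not analysed here, and as etr1-1 carries a point mutation its level would not check the labels.

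The 25 gene lists held 323 genes, of which 48 were measured with a name, so they are thin. The 9 lists with 3 or more measured members were gibberellin receptors and DELLA signalling, genes raised by DELLA proteins, the GASA family, expansins, xyloglucan endotransglucosylases (XTH), ethylene-induced genes, touch and wounding responsive genes, early auxin response and root markers. The 8 lists with fewer were ethylene biosynthesis, ethylene receptors and signalling, abscisic acid and cold response, salicylic acid and defence, the circadian clock, nuclear-encoded photosynthesis, senescence and flavonoid synthesis. The other 8 lists are not analysed here.

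Replicate numbers pair the arrays: for the 18 pairs of arrays at 1 h with the same number in different groups, the correlation across probe sets of the deviations from the group means lay between 0.13 and 0.70, and each of the 12 arrays correlated best with an array of its own number. The numbers come from the labels. The alternatives were an offset of 1, quantile normalization, no filter, no variance trend, an adjusted p of 0.10, the replicate number or the batch as a block, arrays of 1 batch, and leaving out each array in turn. The fits were tested on simulated data made from the means and variances of the arrays at 1 h with 200 changed probe sets per simulation.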

Results

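The series measured transcripts of whole plants of Col-0 and the ethylene-insensitive line etr1-1 after a spray of water or of GA4, and its title asks how gibberellin and ethylene interact in transcription. Groups at 1 h had 3 arrays each, and groups at 0 h, 30 min and 3 h had 1 array each. All arrays were scaled alike, and correlations of the log2 values between arrays at 1 h lay between 0.957 and 0.979 within groups and between 0.950 and 0.989 across groups.

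Over all 5 spray and time conditions, etr1-1 differed from Col-0 most in a small set of genes. QQS, an orphan gene that affects starch content, was 5.14-fold higher in etr1-1 (log2 difference 2.36 ± 0.14, SE, adjusted p = 5.92e-09). ARL, an ARGOS-like gene that promotes cell expansion, was 3.84-fold lower (-1.94 ± 0.11, adjusted p = 3.52e-09). AT5G57760 was 5.37-fold lower (-2.43 ± 0.14) and the jacalin-related lectin gene JAL22 was 2.94-fold lower (-1.55 ± 0.06, adjusted p = 1.66e-11). These folds are ratios of values with the offset added, not of the deposited intensities, and understate the change where a signal is dim. AT5G57760 was dim in etr1-1 (12.4 to 19.7 units over its arrays) and QQS in Col-0 (14.4 to 38.7 units). The size of their folds therefore depends on the offset.

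Other genes higher in etr1-1 over the 18 arrays were AT3G28220 (2.21), AT1G52820 (1.52), AT5G03350 (1.51), AT1G65500 (1.48), AT1G70880 (1.26), AT1G19960 (2.29-fold), AT1G52000 (1.17), AT4G26790 (1.09) and AT1G66100 (1.02), as log2 differences unless given as a fold. The SE was 0.35 for AT3G28220 and 0.11 for AT1G66100. Genes lower in etr1-1 included AT2G39980 (-1.70), AT3G16670 (-1.67), AT5G62280 (-1.63), AT5G22580 (-1.43), AT5G55450 (-1.36), AT2G16005 (-1.22) and AT4G17840 (-1.19 ± 0.07, SE). In limma 1053 of 15922 probe sets passed, 522 higher and 531 lower in etr1-1, and 945 of them had the same sign of difference in all 5 conditions, as had 23.3% of all tested probe sets. The calls come from the same arrays as these signs. Only 22 were over 2-fold higher and 30 over 2-fold lower. With the batch as a block 1837 passed, 958 higher and 879 lower. Within DV001, which holds all 5 conditions, 1323 passed, 757 of them among the 1053. With a replicate block of the array pairs (1 array of each genotype per condition and replicate number) 2286 passed, 1186 higher and 1100 lower, among them all 1053.

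At 1 h after water, QQS was at 228 ± 96.3 units in etr1-1 and 26.6 ± 5.06 in Col-0 (SD, n = 3), and ARL at 56.9 ± 2.04 against 307 ± 99.7. AT5G57760 (-2.63 ± 0.26, SE) and JAL22 (-1.63 ± 0.12) were lower, with adjusted p-values of 3.01e-04 and 2.28e-05. The dioxygenase gene AT1G52820 (1.66), AT5G62130 (1.05) and AT3G51350 (0.69) were higher, and AT2G39980 (-1.75), AT5G62280 (-1.72), AT5G22580 (-1.39), AT5G40590 (-1.32), AT5G44580 (-1.16), AT5G01210 (-1.13) and AT4G17840 (-1.13) were lower. AT1G52800 (1.11, adjusted p = 0.0548), AT4G26790 (1.05), PDF1.4 (1.00), AT2G01580 (0.63) and AT2G24420 (0.56) did not pass, but did with the replicate number as a block (adjusted p = 0.00326, 0.0138, 5.90e-04, 0.0158 and 0.00647). With that block EXPA8 (-0.54 ± 0.36 without it) was also lower in etr1-1 (adjusted p = 0.0348). In limma 37 probe sets passed, 8 higher and 29 lower. With the replicate number as a block 225 passed, 77 higher and 148 lower, and with the batch as a block 105 passed. In DV002 alone 35 passed, and DV001 holds 1 array per group.

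**Figure D1:**
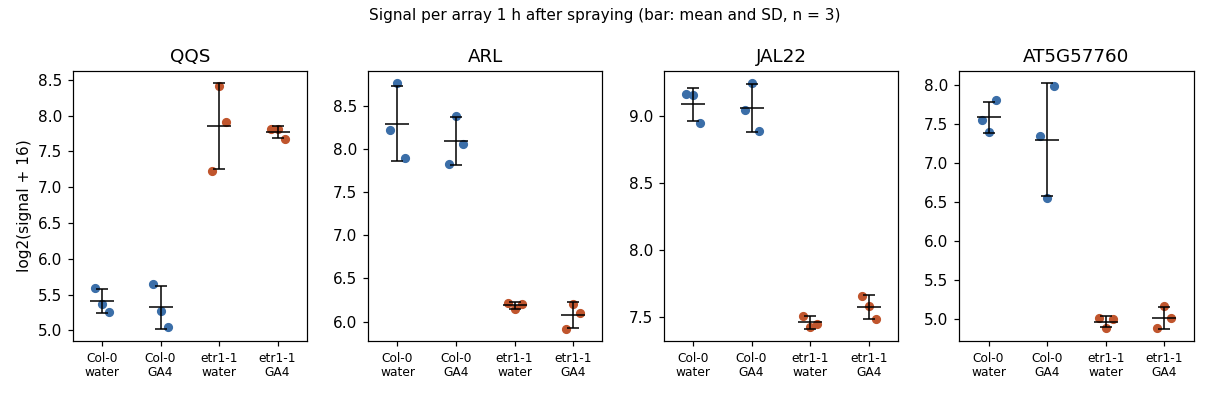
Log2(signal + 16) of QQS, ARL, JAL22 and AT5G57760 on each array at 1 h, with a point per array and the mean and SD of 3 arrays as a bar. QQS is higher on every etr1-1 array than on any Col-0 array, and the other genes are lower on every etr1-1 array.

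After GA4, on arrays that share none with the comparison after water, QQS was at 202 ± 12.5 units in etr1-1 and 24.6 ± 8.51 in Col-0 (SD, n = 3), and ARL at 51.7 ± 6.79 against 260 ± 53.6. AT1G52820 (1.56), AT2G19970 (1.37), AT1G19960 (1.21), GH3.17 (0.78), which conjugates auxin to glutamate, and AT2G21045 (0.63) were also higher in etr1-1. AT5G57760 (-2.29), JAL22 (-1.48), AT5G22580 (-1.42), AT5G62280 (-1.29), AT4G17840 (-1.26), AT5G44580 (-1.10), the formate dehydrogenase gene FDH (-1.08), AT5G26260 (-0.95) and AT5G01210 (-0.94) were lower. In limma 32 probe sets passed, 10 higher and 22 lower. With the replicate number as a block 299 passed, 145 higher and 154 lower, with the batch as a block 135 passed, and in DV002 alone 18 passed. Of the calls after water and after GA4, 5 higher and 20 lower were shared, and all 37 calls after water had the same sign after GA4. Replicate numbers pair the arrays after water with those after GA4, so these are not independent repeats.

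Among ethylene-induced genes with 3 measured members, ARL was lower in etr1-1 in each of these comparisons. RTE1, which acts with the receptor ETR1, had a log2 difference of -0.22 ± 0.09 (SE) over the 18 arrays and PDF1.2b, a defensin gene read by a probe set that may cross-hybridise, had -0.40 ± 0.17, and neither passed over all probe sets. Adjusted over the list alone, all 3 members were lower over the 18 arrays, 1 after water and 2 after GA4. On single arrays RTE1 was lower in etr1-1 at 0 h (log2 6.085 against 6.559). It was not lower at 30 min (6.257 against 6.233) or at 3 h after GA4 (6.44 against 5.986). RTE1 is also in the list of ethylene receptors and signalling. The list was lower by camera over the 18 arrays (adjusted p = 2.06e-04), after water (2.36e-05) and after GA4 (8.51e-05), and adjusted p was 0.0164, 0.0131 and 0.0186 with an estimated correlation. With the replicate number as a block as well as an estimated correlation the call was lost after water (adjusted p = 0.0550) and after GA4 (adjusted p = 0.0639), as it was over the 18 arrays with the replicate block of pairs (adjusted p = 0.0908). After GA4 the touch and wounding list passed only with that block (adjusted p = 0.0387, and 0.235 with an estimated correlation).

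Of 6 measured XTH genes, which remodel cell wall xyloglucan, XTH16 (-0.74 ± 0.09, SE, adjusted p = 6.85e-05) and XTH33 (-0.60 ± 0.16, adjusted p = 0.0279) were lower in etr1-1 over the 18 arrays and 4 did not pass, and adjusted over the list alone the same count of 2 passed. The XTH list passed camera over the 18 arrays (adjusted p = 0.0275) and after water (0.00150), with adjusted p = 0.364 and 0.131 with an estimated correlation. Of the 4 measured GASA genes, GASA7 was higher (0.42 ± 0.06, adjusted p = 3.51e-04) while GASA9 had -0.25 ± 0.15 and did not pass, nor did the list (camera adjusted p = 0.397). DFR, an enzyme of anthocyanin synthesis, was higher (0.45 ± 0.09, adjusted p = 0.00589). No member of the gibberellin receptor and DELLA list passed: GID1A had 0.10 ± 0.09 and GID1B 0.05 ± 0.10. Of the 6 expansin genes none passed over the 18 arrays, and EXPA8 had -0.42 ± 0.20. With the batch as a block EXPA4, EXPA8 and EXPA9 were lower (adjusted p = 0.0351, 0.0473 and 0.0441), as was GASA9 (0.0472). With the replicate block of pairs these 4 genes (adjusted p = 0.0272, 0.00873, 0.0261 and 0.00434) and PDF1.2b (0.0218) were lower, and CML38, a calmodulin-like gene (0.42, adjusted p = 0.00844), was higher. By camera the adjusted p was 0.350 for expansins, 0.397 for genes raised by DELLA proteins, 0.350 for touch and wounding genes, 0.397 for early auxin genes, 0.677 for the gibberellin receptor and DELLA list and 0.677 for root markers. Of these lists, adjusted over the list alone, 1 member was called, the early auxin gene GH3.3 (-0.29 ± 0.11). In the lists with under 3 measured members only DFR was called over all probe sets. Adjusted over the list alone, COR15A, a cold-regulated gene, was also higher (1.38 ± 0.45), and it passed over all probe sets with the batch as a block (adjusted p = 9.11e-04) and with the replicate block of pairs (1.40e-04). No member of the lists of ethylene biosynthesis, ethylene receptors and signalling, salicylic acid and defence, the circadian clock, nuclear-encoded photosynthesis or senescence passed over the 18 arrays. At 1 h, adjusted over the list alone, GASA7 (0.46 and 0.44) and XTH16 (-0.85 and -0.66) passed after water and after GA4, and DFR (0.72) after GA4. LHCB4.1 (0.24 after GA4) is the 1 measured member of its list, so its p of 0.0492 in limma is unadjusted. With the replicate number as a block XTH16 and XTH33 passed over all probe sets after water, and XTH16, DFR and COR15A after GA4.

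GA4 against water at 1 h gave no called gene in either genotype. In Col-0 the gibberellin receptor genes GID1A and GID1B differed by 0.12 ± 0.18 and -0.18 ± 0.20 (log2, SE), GASA9 by 0.06 ± 0.30 and the expansin gene EXPA8 by -0.16 ± 0.36. In etr1-1 GID1A differed by -0.00358, GID1B by -0.05, GASA9 by 0.03 and EXPA8 by 0.31 ± 0.36. The genes with the smallest unadjusted p, none of which passed, were AT2G28580 (0.63), AT4G31330 (0.46), AT4G39050 (0.43), AT3G60290 (0.43) and AT5G66650 (0.34) on the higher side in Col-0, and AT1G10330 (-0.63), AT1G07795 (-0.62), AT1G50575 (-0.38), AT2G16460 (-0.32) and AT2G41170 (-0.29) on the lower side. In etr1-1 they were TSC10B (0.77), AT1G30760 (0.60), DFR (0.54), AT5G26010 (0.37) and AT4G24140 (0.35) on the higher side, and AT4G31330 (-0.51), AT5G07860 (-0.49), AT2G30540 (-0.44), AT5G38890 (-0.41) and AT5G49220 (-0.40) on the lower side. Limma called 0 probe sets in Col-0 and 0 in etr1-1, with 97 and 290 at an unadjusted p under 0.05, where 796.1 would be expected by chance. With the replicate number as a block, 0 passed and 322 and 763 were under 0.05.

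Over both genotypes GID1A differed between GA4 and water by 0.06 ± 0.13, GID1B by -0.11 ± 0.14, GASA9 by 0.04 ± 0.21 and EXPA8 by 0.07 ± 0.26 (log2, SE). The smallest unadjusted p-values belonged to AT4G01380 (0.44), AT1G30760 (0.34), AT5G66650 (0.31), AT5G03600 (0.30) and AT4G24140 (0.24) on the higher side, and to AT1G10330 (-0.63), AT1G07795 (-0.51), AT1G75200 (-0.39), AT1G22270 (-0.31) and AT2G20740 (-0.28) on the lower side, and none passed. Limma called 0 probe sets, with 253 at an unadjusted p under 0.05, and with the replicate block 0, with 794. On the log2(value + 16) scale the 95% interval lay within a 2-fold change for 98.8% of probe sets in Col-0, 98.5% in etr1-1 and 99.7% over both.

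No gene passed the test of a difference in GA4 response between the genotypes. AT4G31330 had the smallest unadjusted p among named genes (-0.97 ± 0.19, SE) and did not pass, nor did AT2G19970 (0.90), AT2G15870 (0.79), AT1G55930 (0.65), AT3G30820 (0.60), AT5G26010 (0.48), AT5G50860 (-0.75), AT3G18295 (-0.62), AT4G38050 (-0.60) or AT5G07860 (-0.60). GID1A had a difference of -0.12 ± 0.25, GID1B 0.14 ± 0.28, GASA9 -0.04 ± 0.42 and EXPA8 0.47 ± 0.51. Limma called 0 probe sets, with 111 at an unadjusted p under 0.05, and 335 with the replicate block, where 0 passed. On the log2(value + 16) scale the 95% interval lay within a 2-fold difference for 94.0% of probe sets, fewer than for GA4 against water in either genotype.

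After GA4 in etr1-1, none of the 6 XTH genes and none of the 3 early auxin genes passed, while both lists passed camera on the higher side (adjusted p = 0.0312 for each). XTH18 had 0.38 ± 0.48 and the auxin conjugation gene GH3.3 0.43 ± 0.21 (log2, SE). Their adjusted p was 0.242 and 0.230 with an estimated correlation, and neither list passed for the difference between the genotypes (camera adjusted p = 0.478 for XTH and 0.263 for auxin). Adjusted over its list alone, which has 2 measured members, DFR passed in etr1-1 (0.54 ± 0.16, adjusted p = 0.00909) and over both genotypes (0.34 ± 0.11, adjusted p = 0.0192). Its difference between the genotypes did not pass (0.40 ± 0.22, adjusted p = 0.190). In Col-0 no list passed. Over both genotypes the ethylene-induced list passed on the lower side (adjusted p = 0.0440, and 0.196 with an estimated correlation), and with the replicate block the XTH list passed too (0.0180). With the replicate block and an estimated correlation neither passed (adjusted p = 0.267 for each). Across probe sets, which are not independent replicates, the GA4 responses of Col-0 and etr1-1 had a Pearson correlation of 0.168 and a Spearman correlation of 0.169, and shared no array. Within replicate numbers 1, 2 and 3 the Pearson correlation was -0.0643, 0.338 and 0.126, with an SD of 0.201. These come from single arrays per group, so their SD is not the error of 0.168, which comes from means of 3. As they differ in sign and no test was run, a correlation other than 0 is not shown. Within the batches the Pearson correlation was 0.126 in DV001, the same arrays as replicate number 3, and 0.0498 in DV002. It was 0.0699 and 0.144 when each genotype came from a different batch. The differences between the genotypes after water and after GA4, on arrays paired by replicate number, had correlations of 0.677 and 0.542.

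At 30 min after GA4, the 3 measured touch and wounding genes were above water at 0 h in both genotypes, in single arrays with no replicate. STZ, a zinc finger gene of the stress response, differed by 2.82 (log2) in Col-0 and 2.66 in etr1-1. CML38 differed by 2.71 and 3.12, and WRKY53 by 1.19 and 0.63. The list's median was 2.71 in Col-0 and 2.66 in etr1-1, above all of the 10000 random lists. At 1 h after water STZ was still 0.88 and 0.56 above 0 h, and at 1 h GA4 and water differed by 0.16 and 0.21 for STZ. EXPA8 was lower at 1 h after water than at 0 h (-1.75 in Col-0 and -1.05 in etr1-1), and at 30 min after GA4 its difference was -1.09 and -0.71. XERICO, in the list of genes raised by DELLA proteins, was lower at 30 min after GA4 than at 0 h (-1.05 in Col-0 and -1.04 in etr1-1). For XERICO the difference from water at 0 h to 1 h was -0.41 and -0.26, and from water to GA4 at 1 h -0.02 and -0.10. It is named after its values were seen.

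In Col-0 all 6 XTH genes were above 0 h at 30 min after GA4, with a median of 1.09, and at 1 h after water, with a median of 0.86. In etr1-1 4 of the 6 were above 0 h at each of these times, with medians of 0.41 and 0.24, and XTH20 was below (-0.55 and -0.48). XTH19 had 1.48 and 0.78 at 30 min. From water at 1 h to GA4 at 3 h the XTH median was -0.55 in Col-0 and -0.44 in etr1-1. Expansins had a median of -0.47 and -0.29 from 0 h to 1 h after water. Of all probe sets, 163 were 2-fold or more higher at 30 min than at 0 h in both genotypes and 4 lower. From water at 0 h to water at 1 h the numbers were 29 and 3, from water to GA4 at 1 h 1 and 1, and from water at 1 h to GA4 at 3 h 7 and 30. GA4 at 30 min and at 3 h had no water spray of the same time among these samples. Steps between 1 h and another time also cross replicate numbers (3 and 1).

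**Figure D2:**
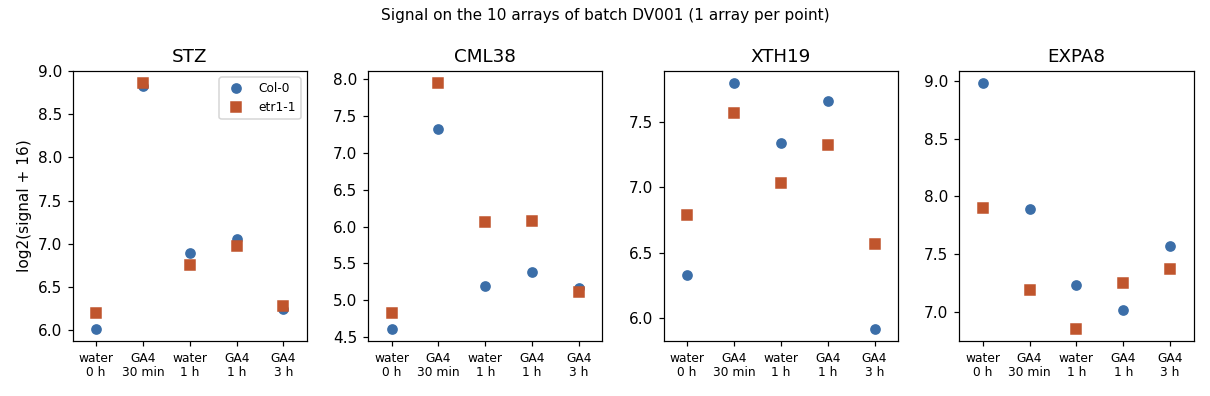
Log2(signal + 16) of STZ, CML38, XTH19 and EXPA8 on the 10 arrays of batch DV001, with a point per array and genotype. STZ and CML38 are highest at 30 min after GA4 in both genotypes, and EXPA8 is highest in water at 0 h.

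The log2 ratios of 3' to 5' control probe sets at 1 h did not pass a test between the genotypes. For GAPDH the mean was 0.45 ± 0.14 in etr1-1 and 0.46 ± 0.36 in Col-0 (SD, n = 6, two-sided exact permutation p = 0.978), for actin 2.41 ± 0.42 and 2.18 ± 0.60 (exact p = 0.470), and for ubiquitin 1.60 ± 0.18 and 1.48 ± 0.22 (exact p = 0.288). Between GA4 and water the lowest of the 36 exact p-values was that of actin, 2.05 ± 0.55 after GA4 and 2.54 ± 0.34 after water (exact p = 0.0952, adjusted p = 1).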

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

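The list tests with the batch as a block, the replicate block of pairs over the 18 arrays and the fit without the arrays of replicate 1 at 1 h were chosen only after the data were seen. No called named gene changed direction under any alternative run. Of the 54 calls of named genes, 8 were lost with no filter, 4 with an offset of 1, 3 with quantile normalization and 3 with no variance trend, none with a block, and in the arrays of DV002 15 of 30 were lost, where fewer arrays were used. Leaving out 1 array at 1 h lost 4 to 11 of the 54 (11 without etr1-1 GA4 replicate 3, 10 without Col-0 GA4 replicate 3 and 10 without etr1-1 GA4 replicate 1). AT3G51350 after water was lost without any 1 of the 12 arrays at 1 h, AT5G22580 after water and AT1G19960 after GA4 without any but 1 of them. Of the calls over all 5 conditions only that of XTH33 was lost when single arrays were left out, without any 1 of 7 arrays (adjusted p from 0.0507 to 0.0687). The number of probe sets differing between the genotypes after water (37) was 57 at an adjusted p of 0.10, 225 with the replicate block and 105 with the batch block. After GA4 (32) it was 299 with the replicate block, 135 with the batch block and 18 in the arrays of DV002. Over all 5 conditions (1053) it was 1619 at an adjusted p of 0.10, 1837 with the batch block and 2286 with the replicate block of pairs. Without the 4 arrays of replicate 1 at 1 h it was 701, of which 615 were among the 1053, and XTH33 no longer passed. Beyond the calls given with the comparisons, the replicate block changed no call between GA4 and water.

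Leaving out each array in turn gave 0 to 1 calls for GA4 in etr1-1 (1 without etr1-1 water replicate 3), 21 to 44 for the genotypes after water (21 without Col-0 water replicate 3 and 22 without etr1-1 water replicate 2), 16 to 37 after GA4 (16 without Col-0 GA4 replicate 3, 19 without Col-0 GA4 replicate 1, 19 without etr1-1 GA4 replicate 1, 21 without etr1-1 GA4 replicate 3) and 703 to 1095 over all conditions. Lists called went from 2 to 0 with an estimated correlation for GA4 in etr1-1. Over both genotypes they went from 1 to 0 with an estimated correlation and with the batch block, and to 2 with the replicate block and with quantile normalization. For the genotypes they went from 2 to 1 with an estimated correlation after water and over all conditions, and from 1 to 2 with the replicate block after GA4. With an offset of 1, the counts of 2-fold differences in both genotypes became 55 higher (from 29) and 7 lower (from 3) from water at 0 h to 1 h, 14 lower (from 4) at 30 min, 2 higher (from 1) and 7 lower (from 1) for GA4 at 1 h, and 11 higher (from 7) and 65 lower (from 30) at 3 h, as a smaller offset widens the folds of dim probe sets.

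Of genes that did not pass, some log2 differences changed sign, and the cause was not tested. For GID1A the GA4 response in etr1-1 was 0.00208 with an offset of 1 and 0.20 in DV002, its difference between genotypes 0.0726 in DV002, and the genotype difference after water -0.0524 in DV002, where GID1B had -0.0244. Leaving out arrays gave these ranges. GA4 in Col-0 ran from -0.20 to 0.37 for GASA9 and from -0.45 to 0.0507 for EXPA8. GA4 in etr1-1 ran from -0.0336 to 0.60 for EXPA8, from -0.16 to 0.25 for GASA9, from -0.22 to 0.15 for GID1A and from -0.16 to 0.0685 for GID1B. The difference in GA4 response ran from -0.0185 to 0.33 for GID1B, from -0.34 to 0.22 for GASA9 and from -0.34 to 0.0349 for GID1A. GA4 over both genotypes ran from -0.0982 to 0.22 for EXPA8, from -0.0527 to 0.13 for GID1A and from -0.0853 to 0.20 for GASA9. The genotypes after water differed by -0.14 to 0.21 for GID1B and -0.49 to 0.0704 for GASA9, after GA4 by -0.0300 to 0.15 for GID1A and -0.41 to 0.22 for EXPA8, and over all conditions by -0.00529 to 0.0936 for GID1B.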

Other observations

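The replicate block at 1 h and the counts within a batch were chosen before the data were seen, but their use as tests of an explanation, the tests of neighbours of ETR1 and of the confidence intervals, the family and plastid comparisons, the replicate block of pairs over the 18 arrays, the exchange of genotypes within pairs, and the fit of the time course over both genotypes were chosen only after the results were seen.

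Beyond the stress genes of the fixed lists, genes higher at 30 min after GA4 included AT4G27280 (log2 3.05 ± 0.15, SE, against water at 1 h, adjusted p = 1.26e-06), AT1G72940 (2.60 ± 0.12) and AT4G29780 (2.23 ± 0.14), named after their values were seen. In this fit the 2 genotypes served as the arrays of each condition within DV001. Its SE, p-values and counts therefore measure how alike the change was in the 2 genotypes, and leave out the spread between replicates. At 1 h after water, CML38 in Col-0 had log2 values of 5.19, 6.373 and 6.965 on arrays of both batches (SE here 0.20). In DV001 the arrays at 1 h carry replicate number 3 and the others 1. Only GA4 against water at 1 h therefore stays within a replicate number. Genes lower at 0 h than at 1 h after water included AT1G19380 (-1.95 ± 0.16), AT2G24600 (-1.94 ± 0.19), EXLA1 (-1.90 ± 0.21), an expansin-like gene, and EXO (-1.64 ± 0.16), while EXPA8 was higher at 0 h (1.40 ± 0.23, adjusted p = 0.00983). At 3 h after GA4 AT1G07050 (1.46 ± 0.14) and COR27, a cold-regulated gene (adjusted p = 4.85e-04), were higher than in water at 1 h. AT2G24600 (-1.95 ± 0.19), AT1G65490 (-1.86 ± 0.22) and EXLA1 (-1.69 ± 0.21) were lower. At 30 min after GA4 AT1G07050 (-0.72) and COR27 (-1.06) were instead lower than in water at 1 h. No water array was sampled at 30 min or 3 h, so GA4 and the time of sampling cannot be told apart in these differences. XERICO was lower at 30 min (-0.71 ± 0.12, adjusted p = 0.0107), while its list of genes raised by DELLA proteins did not pass (camera adjusted p = 0.521). The touch and wounding list was higher at 30 min by camera (adjusted p = 3.53e-11, and 0.0196 with an estimated correlation), and the XTH list was lower at 3 h (adjusted p = 0.00149, and 0.304 with an estimated correlation). The XTH list was also lower at 0 h (adjusted p = 0.00126, and 0.240 with an estimated correlation) and higher after GA4 at 1 h (adjusted p = 0.0403, and 0.932 with an estimated correlation). By the same test expansins were higher at 0 h (adjusted p = 8.18e-05, and 0.0744 with an estimated correlation), and the touch and wounding list was lower at 0 h (3.82e-04, and 0.0744) and at 3 h (0.00409, and 0.257). The limma counts against water at 1 h were 263 probe sets for 0 h, 222 for GA4 at 30 min, 0 for GA4 at 1 h (820 at an unadjusted p under 0.05) and 396 for GA4 at 3 h.

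Of the 69 measured genes of the plastid genome 66 had a negative difference between etr1-1 and Col-0 over the 18 arrays, with a median of -0.37 (log2), and 14 passed the threshold. Among 37 gene families formed from symbols and the plastid genome this was the strongest group by camera (adjusted p = 1.43e-17), but the adjusted p was 0.524 with an estimated correlation. The median was -0.39 with an offset of 1 and -0.34 with quantile normalization. Labelling was primed with oligo(dT), while most plastid transcripts carry no stable poly(A) tail. The mean over these genes in etr1-1 minus that in Col-0 was negative in all 9 pairs of arrays, but its size depended on the arrays (log2). It was -1.03 after GA4 and -0.66 after water in replicate 1 at 1 h, -0.00167 and -0.0461 in replicate 2, and -0.37 and -0.43 in replicate 3. It was -0.0706 at 0 h, -0.19 at 30 min and -0.43 at 3 h. Without the 4 arrays of replicate 1 at 1 h the median was -0.21, 61 of 69 were negative and 6 passed. With the batch as a block 30 passed, and with the replicate block of pairs 35, where the adjusted p was 0.598 with an estimated correlation. No biological explanation was tested for this group.

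The higher signals at 30 min after GA4 may reflect spraying or handling as well as GA4. Probe sets 2-fold or more higher at 30 min in 1 genotype were compared with water at 1 h and 0 h in the other, which shares none of those arrays. The 227 higher in Col-0 had a median of 0.47 in etr1-1 (water 1 h minus water 0 h), and the 226 higher in etr1-1 had 0.57 in Col-0, above all of the matched random lists. At 1 h the highest median of GA4 minus water for these probe sets was 0.0821, which leaves open whether GA4 acts early and briefly. No water array at 30 min is among the samples used, so a part due to GA4 cannot be told apart from spraying at that time. Time of day was not tested, and the step from water at 0 h to 1 h crosses replicate numbers.

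The difference between the genotypes is unlikely to come from a difference between the batches, as each batch held as many arrays of each genotype in each condition. Within DV001 alone 1323 probe sets passed, 757 of them among the 1053. The chromosome segment around ETR1 held 1.16% of the called genes, so most called genes lie outside it. Of 100 genes tested within 200 gene positions on either side 6 were called, against 6.00% elsewhere. Gene positions cannot test whether a variant linked to ETR1 changed genes elsewhere, so that stays open. Of the 6 called in the segment, 5 were higher in etr1-1. Within 50, 100 and 400 positions 8.33%, 9.09% and 5.61% were called (Fisher exact p = 0.653, 0.335 and 1, two-sided). Within 400 positions 11 calls were higher and 1 lower, against 275 and 232 elsewhere (Fisher exact p = 0.0150, two-sided, the lowest of 4 windows), so a linked segment stays open for genes near ETR1. By their locus numbers AT1G65500 and AT1G66100, named above as higher in etr1-1, lie near ETR1. On the 12 arrays at 1 h the largest difference in the 3 ratios of control probe sets was 0.643 of the SD within a genotype. This gives no sign of a difference in RNA quality, but with 6 arrays per genotype it does not exclude one. The highest GAPDH ratio (log2 1.161) was on the Col-0 GA4 array of replicate 1 at 1 h. The pair with that array had the largest difference of the plastid genes (-1.035). The receptor allele, as the biological difference the design names, and any other difference between the lines stay open.

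When genotypes were reassigned within conditions, 1 of 100 splits, the real one, gave as many as 1053 calls, and the highest of the others gave 330. A chance assignment of the 18 arrays is thus unlikely, though 1 of 100 is the lowest share these splits could give. A chance difference between lots of plants was not tested, as the labels do not say whether replicates were grown separately. The real split parts all 9 pairs, as did 18 of the others, which gave at most 145, while the 81 that put both arrays of a pair on 1 side gave up to 330. When genotypes were exchanged only within pairs, 1 of 100 splits, the real one, gave as many calls, and the highest of the others gave 145, or 467 against 2286 with the replicate block of pairs. For the comparisons at 1 h the 10 splits are too few for a share under 0.05: the real counts were 37 after water and 32 after GA4, and the highest of the others was 0 in both (1 of 10 as large), also among the 3 that part all 3 pairs.

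At 1 h no probe set passed between GA4 and water. Variation that both genotypes share by replicate number is an unlikely reason, as the 4 GA4 comparisons gave 0 calls with that block. Variation shared by replicate number within 1 genotype stays open, as a block for each genotype was not fitted at 1 h. With the block 322 probe sets in Col-0 had an unadjusted p under 0.05 in limma, where 796.1 would be expected by chance. Widespread changes of 1 or more in log2(value + 16) are argued against in Col-0, where 98.84% of probe sets had an interval within that change. For dim probe sets a 2-fold change of the intensity is smaller than 1 on this scale, so it is less well covered. In simulations of the comparison in Col-0 on 15922 probe sets, 79.7% of changes of 1 and 15.2% of changes of 0.5 on this scale were called. Each simulation held 200 probe sets changed by 0.5, 1 or 2, and its replicate effects were the same in both genotypes. The shares called hold for that setting and could be lower if fewer probe sets respond. With the replicate block the shares were 93.7% and 42.4%, so smaller responses stay open. For the difference in GA4 response between the genotypes the shares were 43.3% and 0.299%, and 71.0% and 8.66% with the block, so 2-fold differences in response stay open too.

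For the 4 GA4 comparisons the real count was 0, so every split gave as many calls (10 of 10 in Col-0 and in etr1-1, 100 of 100 for the difference in response and over both genotypes) and the splits say nothing about chance. The highest of the other splits gave 0 in Col-0, 0 in etr1-1, 1 for the difference in response and 394 over both genotypes. The split with 394 put the 4 arrays of DV001 on the water side, but whether the batch gave these calls was not tested. With the batch as a block the real count was 0.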
